A study of Homo sapiens with 10 samples.

How the data were processed

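Polyadenylated RNA was measured by sequencing in human umbilical vein endothelial cells (HUVEC), primary cells from the vein of the umbilical cord. The 10 libraries formed 4 groups in 2 experiments. The labels give 80% confluence and 5% fetal bovine serum for each library. In the siRNA experiment, 3 libraries came from cells given a pool of siRNAs against YAP1 (siYAP1) and 3 from cells given a pool without a target (siNC), for 48 h with Lipofectamine 2000. In the adenovirus experiment, 2 libraries came from cells infected for 48 h with a virus that carries YAP with the S127A change (Ad-YAP-S127A) and 2 from cells infected with a control virus (Ad-NC). The labels call this protein catalytically active. The S127A change removes a serine whose phosphorylation by LATS kinases keeps YAP out of the nucleus, so the protein escapes that control. Nothing in the labels says that replicates came from separate donors or cultures, so p-values measure the spread between these libraries, which may be technical in part. RNA was converted with an Illumina TruSeq kit, which does not keep strand, and read as single ends of 100 nt, per the labels' protocols. The sources disagree on the RNA input: the series' design text gives 100 ng and the extract protocol in the labels gives 1 microgram.

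The authors deposited raw read counts per gene symbol, 1 table per experiment, with no normalization. Reads were cleaned with Trimmomatic 0.32, aligned with STAR 2.4.2a to GRCh38.p2 and counted with HTSeq 0.6.1, per the submitters' processing notes, on the GENCODE 23 annotation, per the series' design text. The authors' own tests used DESeq2 1.10.1 and Cufflinks 2.0.2 at an adjusted p of 0.05, per the series' design text. Their results were not used here. The strand setting, the mapping quality filter and the treatment of reads that map to several places are not given in the sources used here. Since strand was not kept, reads of overlapping and antisense genes cannot be told apart. Genes with near-identical copies are uncertain for the same reason of shared reads. A gene with no count in any library of an experiment was absent from that experiment's table. Counts for 25535 genes were given in the siRNA experiment and for 24590 in the adenovirus experiment, and 22566 genes were in both.

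Total counts per library ran from 16432839 (siYAP1 library 3) to 25111635 (siYAP1 library 1), and the total of each library opens the results. A count of 0 in 1 library was compatible with up to 3 counts, which was 0.117 to 0.182 CPM (counts per 1e+06 counts) in the siRNA libraries and 0.137 to 0.153 CPM in the adenovirus libraries. Such floors and all intervals on counts cover counting error alone. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.53 to 28.8 over genes, so no library was counted as a repeat of another. The 28.8 was that of the 2 Ad-NC libraries, and the next highest was 9.88 (siYAP1 libraries 1 and 2). Deviations of the Ad-NC libraries from their mean followed transcript length, with Spearman coefficients of -0.54 (library 1) and 0.54 (library 2). In the Ad-YAP-S127A libraries these were -0.28 and 0.28. With 2 libraries the values of a group mirror each other.

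Each experiment was tested on its own libraries with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after TMM scaling and the filterByExpr filter, with Benjamini-Hochberg adjustment at 0.05 and no term for the replicate number. The filter left 14190 genes in the siRNA experiment and 14564 in the adenovirus experiment. Higher and lower refer to the treated group against its control. Standard errors of log2 fold changes are those implied by the F statistic. CPM values use TMM-scaled library sizes. The biological coefficient of variation, from edgeR's common dispersion, was 4.68% in the siRNA experiment and 10.0% in the adenovirus experiment.

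Before the data were examined, 23 gene lists were fixed: YAP/TAZ target genes, Hippo pathway components, DNA replication and G1/S genes, mitotic genes, NF-kB inflammatory and adhesion genes, interferon-stimulated genes, flow-responsive KLF2/KLF4 genes, endothelial identity genes, Notch pathway genes, angiogenic factors and tip cell genes, TGF-beta and BMP pathway genes, extracellular matrix and remodelling genes, actin cytoskeleton and SRF targets, p53 target genes, unfolded protein and ATF4 response genes, cholesterol synthesis genes, glycolysis genes and MYC, markers of smooth muscle and pericytes, fibroblasts, leukocytes, epithelium and lymphatic endothelium, and mitochondrially encoded genes. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 23 lists. The same test with an estimated correlation, and fry, which asks whether a list's genes move on balance in 1 direction and does not set them against other genes, were alternatives. Where no count adjusted over the list alone is given beside a list, it equals the count over all genes. The groups are small, so the estimated correlation rests on few residual degrees of freedom. The rule for named genes, also fixed then, took YAP1 and WWTR1, the 8 lowest and the 8 highest genes by log2 fold change among called genes with a mean of at least 5 CPM and no overlap of libraries between the groups, up to 4 called members of each list, the 10 genes called in opposite directions in the experiments with the largest smaller change, and the 4 called in the same direction, chosen likewise. The rule passed over antisense genes, pseudogenes without a stated doubt, genes linked to sex and clone-based gene names, and those linked to sex were tested but left out of the written tables. Values of some single genes that the rule names are not reported here.

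The experiments share no library. Overlaps of their calls were tested with Fisher's exact test, two-sided, over the 13686 genes tested in both. Correlations across these genes are descriptions, since genes are not independent replicates. Tests and intervals for overlaps and shares of genes take genes as independent all the same. They do not measure the spread between libraries, and genes that move together make them too narrow. Whether the effect of Ad-YAP-S127A differed from that of siYAP1 was tested as a contrast in an edgeR model of all 10 libraries, in which each gene has a single spread. On simulated data this model made too many false calls, so a version that keeps each experiment's own spread was added: separate fits, with the difference of log2 fold changes set against the combined standard errors.

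The edgeR tests, both versions of the difference of effects and camera were tested on simulated data: counts drawn 10 times for the real genes, with 200 genes changed by 1.5-, 2- or 4-fold in each experiment. These simulations were run after the real comparisons had been seen. Rises and falls were simulated in equal number. The changed genes were a far smaller share than the 27.1% (siRNA) and 54.3% (adenovirus) of tested genes called in the real data. The recovered and false shares below, which also depend on the scaling, may therefore not carry over to the real calls. Of the genes changed by 1.5-fold, 2-fold and 4-fold, edgeR recovered 87.2%, 96.3% and 100% in the siRNA design (13936 to 13978 genes) and 42.2%, 84.6% and 98.8% in the adenovirus design (14054 to 14072 genes). False calls were 7.54% of calls in the siRNA design (5.58% to 10.3% over the simulations) and 5.83% in the adenovirus design (1.90% to 10.5%). Both pooled shares were above the nominal 5%, but the range in the adenovirus design spanned it. For the difference of effects, the model of all 10 libraries recovered 79.0% with 14.6% false calls (13673 to 13683 genes), and the version with separate spreads recovered 75.2% with 6.71% false calls (13333 to 13371 genes). Camera called a list of 20 genes raised by 1.5-fold in 10 of 10 simulations and 0 of 200 random lists in either design. The simulated genes varied independently, so this does not test camera on genes that vary together.

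Alternatives covered DESeq2 1.42.0, limma-voom, other scalings and filters, counts thinned to the smallest library, a replicate block, a fit of all 10 libraries, and leaving out each replicate. Chosen after seeing the data were the removal of trends with GC content and transcript length, with and without the block, a run without siYAP1 libraries 2 and 3, a run without YAP1 in the adenovirus table, and the separate spreads above. The trend removal takes out any part of a group difference that follows GC content or length as well. GC content, length and gene positions came from GENCODE 44 on GRCh38, matched by symbol. Of all 27559 symbols 69.5% matched, and of the tested genes 87.5% in the siRNA and 86.9% in the adenovirus experiment. CTGF and CYR61 are given by the older symbols of the tables and without positions.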

Results

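RNA from 10 HUVEC libraries was compared in 2 experiments: loss of YAP1 with siYAP1 against siNC (3 libraries each) and gain of YAP activity with Ad-YAP-S127A against Ad-NC (2 libraries each). YAP1 and its paralog TAZ, the product of WWTR1, are co-activators that bind TEAD transcription factors and are held back by the Hippo pathway. The series asks which genes respond to YAP in endothelial cells. Total counts per library were 20271724, 21903948 and 22628029 for siNC, 25111635, 21027954 and 16432839 for siYAP1, 22062600 and 21092943 for Ad-NC, and 20532301 and 20786143 for Ad-YAP-S127A.

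YAP1 (ENSG00000137693.14, GRCh38 chromosome 11, 102110447 to 102233424, plus strand) fell from 65.6 ± 2.50 CPM (SD, n = 3) in siNC to 6.45 ± 0.326 CPM in siYAP1, 9.83% of control. The log2 fold change was -3.35 with an SE of 0.07 (edgeR, adjusted p 6.45e-16). The values per library were 68.3, 65.0 and 63.4 CPM in siNC and 6.58, 6.07 and 6.68 CPM in siYAP1. WWTR1 (GRCh38 chromosome 3, 149517235 to 149736714) had a log2 fold change of -0.20 with an SE of 0.05 (edgeR, adjusted p 0.00596), a call that ended without siYAP1 library 3 (adjusted p 0.0501) and without siYAP1 libraries 2 and 3 (0.132; log2 fold change -0.16).

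**Figure D1:**
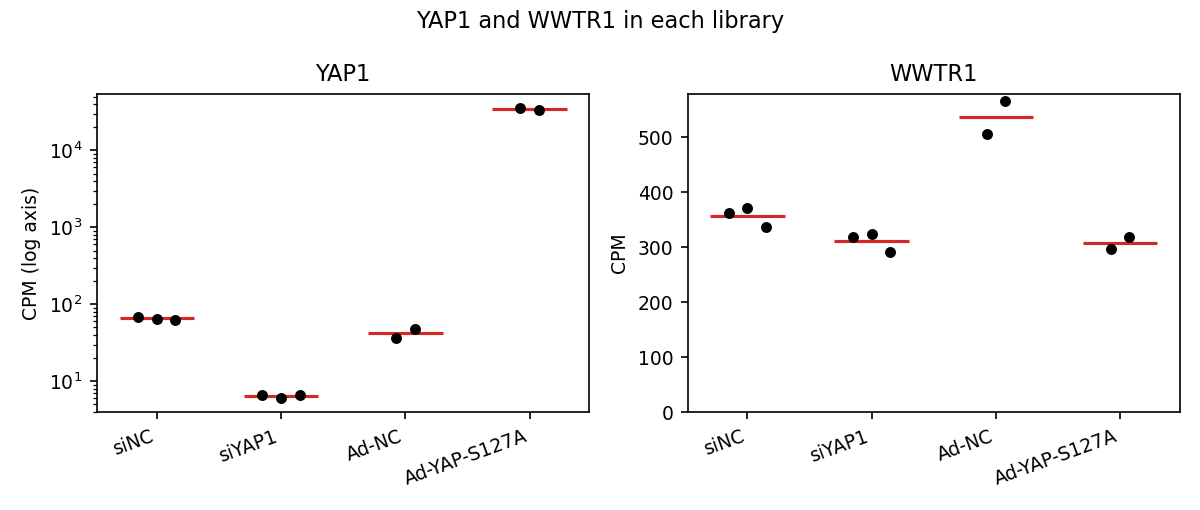
CPM of YAP1 (left, log axis) and WWTR1 (right, linear axis) in each of the 10 libraries, with points for libraries and red lines for group means. YAP1 lies between 6.07 and 6.68 CPM in the 3 siYAP1 libraries and at 35602 and 33584 CPM, with transgene reads included, in the Ad-YAP-S127A libraries.

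Beyond YAP1, the largest falls after siYAP1 among called genes with a mean of at least 5 CPM and no overlap of libraries between the groups were those of TGFB2, a TGF-beta ligand (GRCh38 chromosome 1, 218345336 to 218444619; log2 fold change -2.92, SE 0.15, adjusted p 2.07e-10), GDF6, a BMP family ligand (-2.66, SE 0.09), SULF1, an extracellular heparan sulfatase (-2.65, SE 0.16), and PLOD2, a collagen lysyl hydroxylase (-2.55, SE 0.06). PLOD2 went from 1060 ± 72.9 to 181 ± 9.99 CPM (SD, n = 3). KRT7 (-1.84), CCNA1 (-1.83) and TNFRSF21 (-1.47) followed in that set. The largest rises in it were those of CEND1 (2.45, SE 0.12), LYVE1, the hyaluronan receptor of lymphatic endothelium (1.87, SE 0.09; 10.4 ± 1.56 to 38.0 ± 2.01 CPM), VAT1L (1.62), SERPINB2 (1.58), FAM107A (1.57), AOX1 (1.51), KCNMB1 (1.48) and IGFBP6 (adjusted p 3.27e-08). All of these passed the edgeR test, with adjusted p values of 1.14e-07 or below. In all, 1973 genes were higher and 1870 lower among 14190 tested, and 2312 and 1551 with library totals alone in place of TMM scaling. Most changes were small: the median absolute log2 fold change of called genes was 0.29, and 156 higher and 78 lower genes changed by at least 2-fold. Without siYAP1 libraries 2 and 3, which held more RNA without a poly(A) tail, 1060 were higher and 892 lower. That run left 1 siYAP1 library, which was assumed to vary like the siNC libraries, so its spread came from siNC alone.

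Of 21 cholesterol synthesis genes 18 were lower after siYAP1 and 0 higher, with a median log2 fold change of -0.39 (camera adjusted p 1.40e-10; adjusted p 0.142 with an estimated correlation). SREBF2, the transcription factor that drives this pathway, was at -1.02 (SE 0.05), HMGCS1 at -0.77, IDI1 at -0.64 and SQLE at -0.58. TGF-beta and BMP pathway genes were lower as a list, with 14 of 23 lower and 3 higher (4 higher and 14 lower when adjusted over the list alone; camera adjusted p 0.000549; adjusted p 0.136 with an estimated correlation). They included TGFB2, the ligand BMP4 (-1.17, SE 0.06), the activin subunit INHBA (-1.13, SE 0.08) and TGFBI (-0.83, SE 0.05). Of 21 p53 target genes 11 were lower and 1 higher (14 lower and 1 higher when adjusted over the list alone; camera adjusted p 0.000549; adjusted p 0.136 with an estimated correlation). Among them the cell cycle inhibitor CDKN1A was at -0.75, the p53 ubiquitin ligase MDM2 at -0.44 and TP53INP1 at -0.39. Glycolysis genes and MYC had 9 of 22 lower and 0 higher (11 lower when adjusted over the list alone), with SLC2A1, a glucose transporter, at -0.40 and LDHA at -0.26 (camera adjusted p 0.00908; adjusted p 0.753 with an estimated correlation; fry adjusted p 0.0910). NF-kB inflammatory and adhesion genes had 9 of 21 lower and 0 higher, including the leukocyte adhesion receptor SELE (-1.81, SE 0.24), the chemokines CCL2 (-1.25) and CXCL8 (-0.68), and the prostaglandin synthase PTGS2 (-0.94). That list's call (camera adjusted p 0.0442, and 0.688 with an estimated correlation) ended without siNC library 1 (adjusted p 0.177) or siYAP1 library 1 (0.0717), and with the replicate block (0.0725). It also ended with GC and length trends removed (0.0618, and 0.113 with the block as well) and with camera on ranks (0.117). Of 5 epithelial markers 4 were lower and 1 higher, with KRT7 at -1.84, KRT18 at -0.57 and KRT8 at 0.43, the last no longer called without siYAP1 libraries 2 and 3 (0.36, adjusted p 0.0538; for the list camera adjusted p 0.0389; adjusted p 0.527 with an estimated correlation). The list's call ended without siNC library 2 (camera adjusted p 0.0796) and with the replicate block (0.0701, and 0.0851 with GC and length trends removed as well). It also ended in the fit of all 10 libraries (0.148), without a filter (0.0953) and with camera on ranks (0.117). With an estimated correlation 0 of 23 lists passed, 3 had an unadjusted p under 0.05, and fry called 9.

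The YAP/TAZ target list was not called after siYAP1: 8 of 21 were lower, 4 higher and 9 not called (5 higher and 8 lower when adjusted over the list alone, camera adjusted p 0.673). Its members are targets described across cancer cell lines, not in endothelial cells. TGFB2, ANKRD1 (-0.81, SE 0.09), CTGF (-0.51, SE 0.05), AMOTL2 (-0.27, SE 0.04) and CYR61 (-0.16, SE 0.04) were lower, while F3, which encodes tissue factor (0.94, SE 0.13), and NT5E, an ecto-nucleotidase (0.56, SE 0.04), were higher. Hippo pathway components went both ways, with 5 of 24 higher and 7 lower (6 and 7 when adjusted over the list alone; camera adjusted p 0.673). FRMD6 (-0.79) and NF2 (-0.75), upstream members of the pathway, were lower and VGLL3, a TEAD cofactor, was higher (0.57).

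Flow-responsive genes also went both ways, with 6 of 11 higher and 4 lower (camera adjusted p 0.175). KLF2, a transcription factor induced by shear stress, rose from 17.1 ± 1.46 to 39.9 ± 2.80 CPM (SD, n = 3; log2 fold change 1.22, SE 0.07) and HMOX1 rose by 0.92 (SE 0.07). Endothelial identity genes had 7 of 25 higher and 7 lower (8 and 7 when adjusted over the list alone; camera adjusted p 0.834), with TEK (0.51) and FLT1 (0.48) higher and LYL1 (-0.58) and MMRN1 (-0.53) lower. Notch pathway genes had 6 of 15 higher and 6 lower (adjusted p 0.673), with NOTCH4 at 0.97 and HES4 at -0.80. Angiogenic factors and tip cell genes had 4 of 18 higher and 6 lower (5 and 8 when adjusted over the list alone; adjusted p 0.377), with ANGPT1 at -0.94 and NRP2 at 0.55. HES4 and ANGPT1 were no longer called without siYAP1 libraries 2 and 3 (-0.61 and -0.81, adjusted p 0.104 and 0.0515), nor HES4 in the fit of all 10 libraries (0.0522). Extracellular matrix genes had 7 of 33 higher and 12 lower (8 and 12 when adjusted over the list alone; adjusted p 0.565), with COL8A1 at -1.34, FN1 at -0.67 and FBN1 at 1.10. The median of that list was 0.02 while its mean was -0.04 and the test pointed down. Actin cytoskeleton and SRF targets had 4 of 26 higher and 10 lower (adjusted p 0.0652), with DLC1 at -0.81 and MYL9 at 0.47.

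Neither list of cell cycle genes was called after siYAP1. DNA replication and G1/S genes had 5 of 25 higher and 5 lower (9 and 5 when adjusted over the list alone; camera adjusted p 0.558), with RRM2 at -0.29 and MCM5 at 0.27. Mitotic genes had 1 of 25 higher and 3 lower (adjusted p 0.177), with CDC20 at -0.29 and TPX2 at -0.19, and the list passed without siNC library 2 (adjusted p 0.0468). Neither gene was called in the fit of all 10 libraries (adjusted p 0.0882 and 0.110), and TPX2 was not without siYAP1 libraries 2 and 3 (-0.18, adjusted p 0.0970). Interferon-stimulated genes had 8 of 30 higher and 3 lower (adjusted p 0.177), with OAS2 at 0.87, IFITM1 at 0.78 and CMPK2 at -0.87, none of the 3 called without siYAP1 libraries 2 and 3 (0.72, 0.77 and -0.72 there, adjusted p 0.0526, 0.0516 and 0.0750). Unfolded protein and ATF4 response genes had 3 of 20 higher and 8 lower (5 and 8 when adjusted over the list alone; adjusted p 0.0841), with ATF3 at -1.05 and DDIT4 at -0.64. That list passed without siNC library 2, at 0.0468. Markers of other cell types gave no further call. Lymphatic endothelial markers had 2 of 4 higher and 0 lower (LYVE1 and PROX1, the latter at 0.51 and no longer called with thinned counts, adjusted p 0.0611, or in the fit of all 10 libraries, 0.109; 0.175 for the list), smooth muscle and pericyte markers 1 of 5 higher and 1 lower (ACTA2 at 0.51, no longer called without siYAP1 library 1, adjusted p 0.0670, and RGS5 at -0.33; 0.673 for the list), and leukocyte markers 1 of 3 higher and 1 lower (LAPTM5 at 0.19, SRGN at -0.39; 0.697). Of 6 fibroblast markers edgeR called 0 (1 at an unadjusted p under 0.05 and 0 by DESeq2; camera adjusted p 0.673). COL3A1 was at 0.17 and COL1A2 at -0.13, neither past the test, though COL3A1 passed without siYAP1 libraries 2 and 3 (adjusted p 0.0323). Mitochondrially encoded genes, a sign of RNA quality, had 3 of 13 higher (MT-ND1, MT-CO1 and MT-CO3, none of them called without siNC library 2, with adjusted p 0.177, 0.138 and 0.179, nor without siNC library 3 or siYAP1 library 1 or 3) and 0 lower (camera adjusted p 0.175, and 0.000982 without siYAP1 library 2 and 0.0161 with the replicate block). Counts from them were 1.98% to 2.30% of siNC and 2.08% to 2.62% of siYAP1 libraries.

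In the adenovirus experiment, YAP1 rose from 36.8 and 47.9 CPM in the Ad-NC libraries to 35602 and 33584 CPM in the Ad-YAP-S127A libraries, where it took 3.79% and 3.46% of all counts. The log2 fold change was 9.67 with an SE of 0.20 (edgeR, adjusted p 6.98e-07). Reads of the transgene's coding part count towards YAP1, so the value gives no level of the cell's own gene. The processed pseudogene YAP1P1 had 0 counts in Ad-NC and 190 in Ad-YAP-S127A, at least 60.1-fold against a floor of 3 counts over the group, a sign of reads shared with that copy. WWTR1 was at -0.80 (SE 0.11, adjusted p 0.000471).

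Among called genes with a mean of at least 5 CPM and no overlap of libraries between the groups, the lowest fitted fold changes with Ad-YAP-S127A were those of APLNR, GJA4, APOL4, KIT, SLCO2B1, APCDD1, AQP1 and GJA5. APLNR, the apelin receptor, went from 3105 counts over the Ad-NC group to 1 count, a ratio of 3270 (exact 95% interval 586 to 129199, counting error only). GJA4 (GRCh38 chromosome 1, 34792999 to 34795747), an arterial connexin, had 507 counts in Ad-NC and 0 in Ad-YAP-S127A, at least 178-fold lower, and APOL4 had 459 and 0, at least 161-fold lower, with the floor of 3 counts taken over the group. KIT had 1399 and 2 counts (ratio 737, 204 to 6089), SLCO2B1 478 and 1 (ratio 503, 89.9 to 19924) and APCDD1 645 and 2 (ratio 340, 93.6 to 2811). The water channel AQP1 (-9.08, SE 0.27) and the arterial connexin GJA5 (-8.13, SE 0.39) also fell. Apart from YAP1, a clone-named gene and an antisense gene, the highest in that set were HOXB13, a posterior HOX gene with 2 counts in Ad-NC and 441 in Ad-YAP-S127A (ratio 209, 57.6 to 1734), AREG, an EGF receptor ligand (6.55, SE 0.29; 0.214 ± 0.158 to 21.0 ± 1.36 CPM, SD, n = 2), the neutrophil chemokines CXCL8 (4.49, SE 0.21) and CXCL5 (4.24, SE 0.28), HCN2 (4.47), HSPB6 (4.41) and VASN (3.97). All passed the edgeR test, with adjusted p values of 1.92e-05 or below. Of 14564 tested genes 3845 were higher and 4063 lower, 1284 and 1995 of them by at least 2-fold, and the median absolute log2 fold change of called genes was 0.85. The higher genes numbered 2373 without Ad-YAP-S127A library 1 and 2538 without library 2. Scaling by library totals alone moved the median log2 fold change of all genes to 0.14 and the share of higher genes among calls from 48.6% to 59.0% (4765 higher, 3317 lower), so directions are relative to the TMM scale.

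Of 25 endothelial identity genes 20 were lower with Ad-YAP-S127A and 0 higher (21 lower when adjusted over the list alone), with a median log2 fold change of -1.69 (camera adjusted p 3.88e-07; adjusted p 0.608 with an estimated correlation). KDR, the main VEGF receptor (GRCh38 chromosome 4, 55078481 to 55125595), went from 831 ± 253 to 14.7 ± 2.83 CPM (SD, n = 2; log2 fold change -5.82, SE 0.26), the tight junction gene CLDN5 from 57.5 ± 2.43 to 1.41 ± 0.143 CPM (-5.35, SE 0.15), and EMCN and CD34, surface sialomucins, were at -2.84 and -2.74. Notch pathway genes had 9 of 14 lower and 2 higher (camera adjusted p 0.0114; adjusted p 0.648 with an estimated correlation), with HEY1 at -3.05 and the ligands DLL4 at -2.69 and DLL1 at -2.35. Of 21 p53 target genes 15 were lower and 1 higher (camera adjusted p 0.00160; adjusted p 0.608 with an estimated correlation), with TP53INP1 at -2.46, BTG2 at -1.62 and BBC3 at -1.53, while CDKN1A was at 0.43.

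Mitotic, DNA replication and cholesterol synthesis genes were called higher as lists by camera with the preset correlation. Mitotic genes had 15 of 25 higher and 0 lower (median log2 fold change 0.61; camera adjusted p 0.00173; adjusted p 0.728 with an estimated correlation; fry adjusted p 0.163), with the kinase PLK1 at 1.41 (SE 0.22) and CENPE at 1.03 (SE 0.22). CDCA8 (1.11) and MKI67 (0.96) were no longer called without Ad-YAP-S127A library 2 (adjusted p 0.0958 and 0.0896). DNA replication and G1/S genes had 12 of 25 higher and 3 lower (camera adjusted p 0.0146; adjusted p 0.707 with an estimated correlation; fry adjusted p 0.0570), with MCM6 at 1.47, GINS2 at 1.38, CDC6 at 1.37 and MCM7 at -1.31. Cholesterol synthesis genes had 14 of 21 higher and 1 lower (15 and 1 when adjusted over the list alone; camera adjusted p 0.00161; adjusted p 0.707 with an estimated correlation), with ACAT2 at 1.45 (SE 0.13) and FDFT1, the squalene synthase, at 0.89 (SE 0.10). With an estimated correlation 0 of 23 lists passed, 1 had an unadjusted p under 0.05, and fry called 11.

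The YAP/TAZ targets CTGF and CYR61, matricellular genes, rose with Ad-YAP-S127A from 614 ± 121 to 4410 ± 84.0 CPM and from 357 ± 100 to 2213 ± 62.3 CPM (SD, n = 2; log2 fold changes 2.84 and 2.63, SE 0.15 and 0.18). The list had 10 of 21 higher and 7 lower (camera adjusted p 0.375), with NT5E at -1.93 and IGFBP3 at -1.94. Hippo pathway components had 10 of 24 higher and 5 lower (12 and 5 when adjusted over the list alone; adjusted p 0.0911), with TEAD3 at 1.61 and AMOTL2 at 1.56, and the list passed without Ad-NC library 2 (0.0292) or Ad-YAP-S127A library 1 (0.0476). NF-kB inflammatory and adhesion genes had 8 of 21 higher and 9 lower (adjusted p 0.822). The chemokines CXCL6 (5.00), CXCL8, CXCL5 and CXCL1 (2.25) rose and CCL2 (-2.17) and SELE (-1.48) fell, and the median of -0.34 and the mean of 0.40 differed in sign, with the test pointing up. Interferon-stimulated genes had 10 of 29 higher and 12 lower (adjusted p 0.727), with OAS2 at -3.95, OAS1 at -2.89 and IFIT1 at 2.38.

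Flow-responsive genes had 7 of 12 lower and 2 higher (camera adjusted p 0.101; median -0.55, and -0.55 with GJA4 at its bound), with CYP1A1 at -2.17 and KLF2 at -0.40. Angiogenic factors and tip cell genes had 11 of 19 lower and 3 higher (11 and 4 when adjusted over the list alone; adjusted p 0.0927), with CXCR4 at -2.95, NRP2 at -2.25 and ANGPT2 at -2.03, and the list passed without Ad-NC library 2 (0.0472). Extracellular matrix genes had 18 of 33 lower and 7 higher (adjusted p 0.0802; 0.0304 without Ad-NC library 1), with TIMP3 at -4.52, TNC at -2.60, COL4A1 at -2.17 and COL8A1 at 1.79. TGF-beta and BMP pathway genes had 5 of 23 higher and 7 lower (adjusted p 0.912), with TGFB2 at 1.60, BMPER at -2.12 and the receptors TGFBR1 at -1.37 and TGFBR2 at -1.23. The median of that list was 0.16, its mean -0.09 and its test pointed down. Actin cytoskeleton and SRF targets had 10 of 26 higher and 8 lower (adjusted p 0.618), with MYL9 at 1.14 and LIMCH1 at -4.57. The median of 0.12 and camera pointed up, the mean of -0.12 and fry down. Unfolded protein and ATF4 response genes had 1 of 20 higher and 9 lower (0.263), with DDIT4 at -2.62 and VLDLR at -1.94. Glycolysis genes and MYC had 5 of 22 higher and 7 lower (0.791), with HK2 at -1.32 and ALDOC at 0.99.

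Of the marker lists, lymphatic endothelial markers had 3 of 4 lower and 0 higher (LYVE1 at -6.18, PROX1 at -2.41, FLT4 at -1.96; camera adjusted p 0.0802, and 0.0472 without Ad-NC library 2). Fibroblast markers had 5 of 7 lower and 1 higher (5 and 2 when adjusted over the list alone; adjusted p 0.149), with PDGFRA at -4.03 and COL1A1 at 2.99. Epithelial markers had 3 of 6 higher and 1 lower (0.496), with the keratins KRT18 at 3.04, KRT7 at 1.70 and KRT8 at 0.69. Smooth muscle and pericyte markers had 3 of 6 higher and 2 lower (0.755), with TAGLN at 0.93 and NOTCH3 at 0.92. Leukocyte markers had 0 of 3 higher and 1 lower, LAPTM5 at -1.80 (0.609; median 0.02, mean -0.54 and the test down). Mitochondrially encoded genes had 1 of 13 higher and 0 lower by edgeR, MT-ND2 at 0.34 (adjusted p 0.0389, and 0.286 without Ad-YAP-S127A library 1 and 0.0828 without Ad-NC library 2), and 0 when adjusted over the list alone (0.609).

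**Figure D2:**
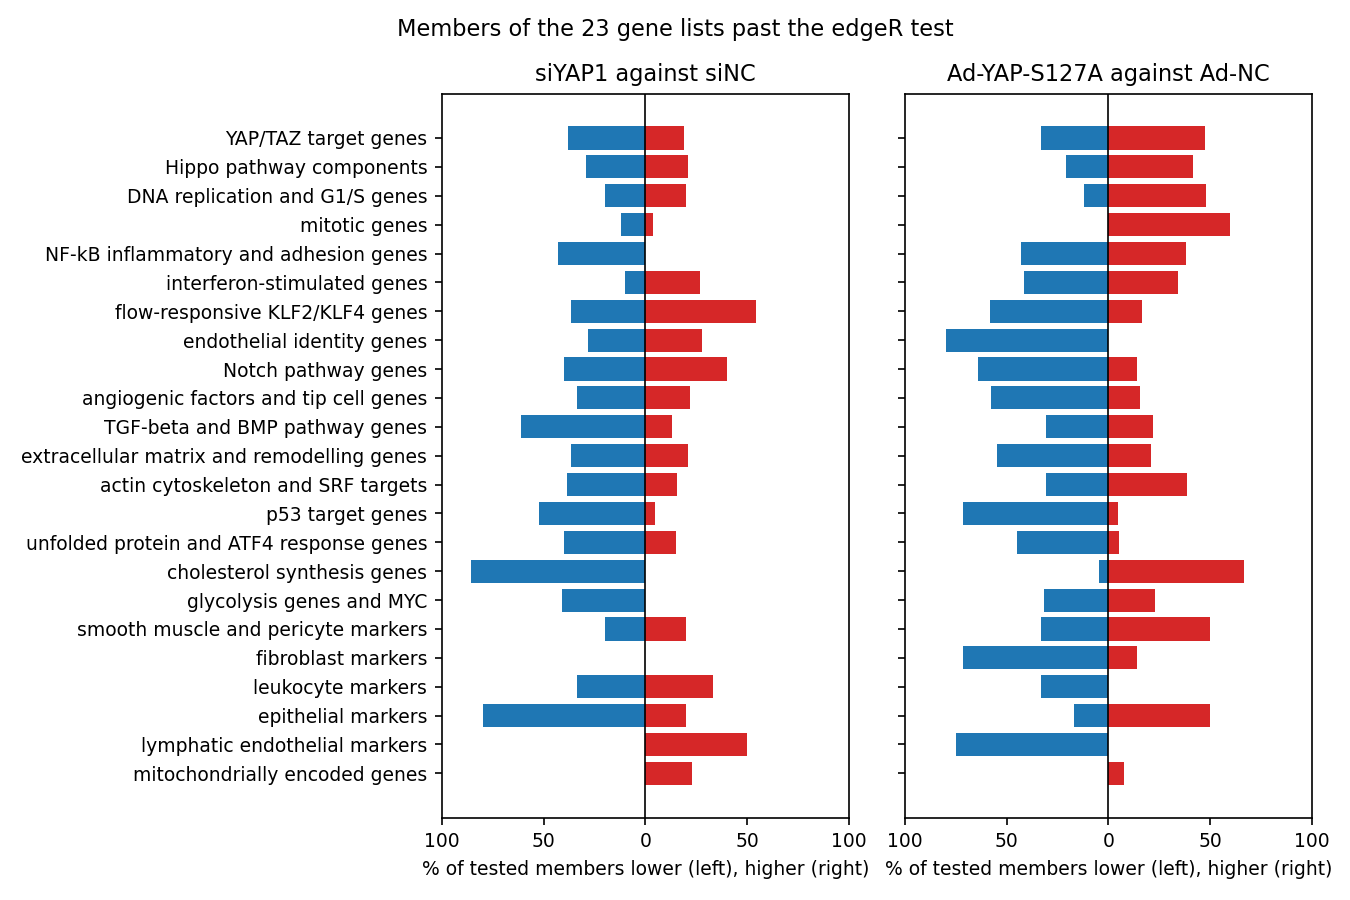
Share of the tested members of each of the 23 gene lists that was lower (blue, left) or higher (red, right) by the edgeR test, in percent, after siYAP1 (left panel) and with Ad-YAP-S127A (right panel). Cholesterol synthesis genes had 18 of 21 members lower on the left and 14 of 21 higher on the right, and endothelial identity genes had 20 of 25 lower on the right.

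Of 21 YAP/TAZ targets tested in both experiments 5 were called lower after siYAP1 and higher with Ad-YAP-S127A: TGFB2, ANKRD1, CTGF, CYR61 and AMOTL2. Another 4 were called in the same direction in both, AXL and LATS2 higher, CCDC80 and GADD45A lower, and 1, NT5E, was called higher after siYAP1 and lower with Ad-YAP-S127A. With or without calls, 9 of the 21 had opposite signs. Outside that list, KRT7 was lower after siYAP1 (-1.84) and higher with Ad-YAP-S127A (1.70). LYVE1 (1.87 and -6.18), CBLN2 (2.04 and -4.06), SCUBE1 (1.79 and -4.12), VAT1L (1.62 and -3.11), HGF (2.21 and -2.77), CETP (2.30 and -2.40), FAM167B (1.73 and -2.34) and CDA (1.68 and -1.98) went the other way, higher and then lower. Named for the same direction were NOG (-2.05 and -2.12) and GJA5 (-1.87 and -8.13), lower in both, and AOX1 (1.51 and 4.79) and WNK4 (1.77 and 2.36), higher in both. All of these values passed the edgeR test of their experiment, with adjusted p values of 0.00545 or below. The rule for genes called in both experiments set no minimum CPM. After siYAP1, CBLN2, SCUBE1, HGF, CETP, FAM167B, CDA, WNK4, NOG and GJA5 were outside the set above. That set required a mean of at least 5 CPM and no overlap of libraries between the groups.

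**Figure D3:**
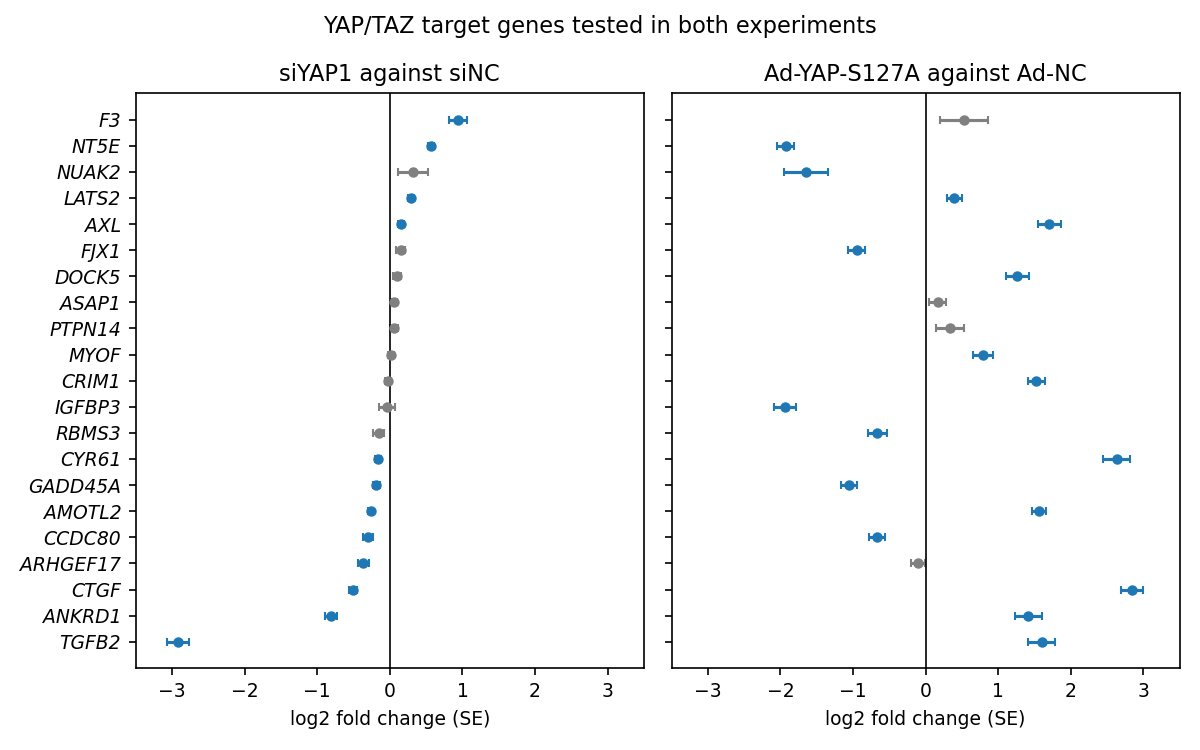
Log2 fold changes with their SE of the 21 YAP/TAZ target genes tested in both experiments, after siYAP1 (left) and with Ad-YAP-S127A (right), ordered by the left panel, with points that passed the edgeR test in blue and others in grey. TGFB2, ANKRD1, CTGF, AMOTL2 and CYR61 lie left of 0 on the left and right of 0 on the right.

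Among 13686 genes tested in both experiments, 498 were lower after siYAP1 and higher with Ad-YAP-S127A, where independent lists would share 491 (odds ratio 1.02, 95% interval 0.914 to 1.14, Fisher's exact test adjusted p 0.692). The overlap was 330 without Ad-YAP-S127A library 1 (odds ratio 1.13). Its unadjusted p fell under 0.05 with DESeq2 (370 against 332, odds ratio 1.17, p 0.0133), without siNC library 2 (odds ratio 1.17, p 0.00923) and without siYAP1 library 3 (odds ratio 1.14, p 0.0293). The reverse pair, higher and then lower, held 690 genes against 530 (odds ratio 1.58, 1.42 to 1.75, adjusted p 1.35e-17). Lower in both experiments were 675 genes against 510 (odds ratio 1.62, 1.46 to 1.80, adjusted p 1.05e-18), and higher in both 527 against 510 (odds ratio 1.06, adjusted p 0.439). The last overlap passed without Ad-NC library 2 (565 genes, odds ratio 1.21, unadjusted p 0.000644) and without Ad-YAP-S127A library 1 (359 genes, odds ratio 1.21, unadjusted p 0.00384), and was 347 without Ad-YAP-S127A library 2. Of 2389 genes other than YAP1 called in both, 49.7% changed in opposite directions. Of the 96 that changed by at least 2-fold in both, 64 did (66.7%, exact 95% interval 56.3% to 76.0%). The share expected from independent directions was not computed and need not be an even split. Rises and falls of at least 2-fold were uneven: 156 and 78 after siYAP1, 1284 and 1995 with Ad-YAP-S127A. The tests and intervals in this paragraph take genes as independent and measure no spread between libraries. Log2 fold changes correlated across genes with a Pearson coefficient of -0.050 and a Spearman coefficient of -0.007.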

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

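The tests of explanations below the difference of effects, the version of that test with separate spreads and the share of list members used to describe it were chosen after the results were seen, except the splits of the libraries, the histone genes and the strata of expression, which were written down before their values were known. For the histone genes the rise of the siYAP1 group had been seen, and the value within the group had not.

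The effects of Ad-YAP-S127A and siYAP1 differed, by a test of the difference itself, for 54.8% of genes. In the edgeR model of all 10 libraries, 4146 of 15316 genes had a higher effect of Ad-YAP-S127A and 4240 a lower one. The same model made 14.6% false calls on simulated data. With the spread of each experiment kept apart, a version added after that was seen, 3582 of 13686 genes had a higher and 3705 a lower effect, and 7247 genes were called by both versions in the same direction. At least 75% of the members differed in 1 direction in 3 of the lists with 10 or more members, and in 2 with the spreads kept apart. Mitotic genes had 19 of 25 members with a higher effect of Ad-YAP-S127A and 0 with a lower one, and 16 and 0 with the spreads kept apart. Endothelial identity genes had 19 of 25 with a lower effect of Ad-YAP-S127A and 1 with a higher one in either version. Cholesterol synthesis genes had 19 of 21 with a higher effect and 1 with a lower one, and 18 and 1 with the spreads kept apart. The experiments differ in the route of delivery and in their controls as well as in the direction of the YAP change. These are therefore differences between whole experiments. A gene that follows YAP in both differs here, as does a gene changed by 1 treatment only. With Ad-YAP-S127A alone 54.3% of tested genes were called. In the main list tests, cholesterol synthesis genes were called in both experiments, in opposite directions (median log2 fold changes -0.39 and 0.46). The p53 target genes were called in both as well, but lower in each (median log2 fold changes -0.16 and -0.60). Mitotic and endothelial identity genes were called with Ad-YAP-S127A only.

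The 6 siRNA libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 3843 genes, was 1 of 10 with as many, and the highest of the other splits called 0 by edgeR (398 at an unadjusted p under 0.05, against 5299). For the gene lists, the real split called 6, was 1 of 10 with as many, and the highest of the other splits called 5. With an estimated correlation 0 lists passed in the real split. Every other split put siNC and siYAP1 libraries in both of its groups. An effect of the treatment would widen the spread within those groups and leave part of the contrast between them. Few gene calls were thus to be foreseen there, and the list calls there are not those of untreated libraries. The splits therefore decide nothing about how the real calls arose.

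RNAs that lack a poly(A) tail were higher in part of the siYAP1 libraries. The 6 RNAs examined, RN7SK, RMRP, RPPH1, RN7SL1, SNORA73B and the mitochondrial rRNA MT-RNR1, were picked because they rose, from a class of 16 tested small or untailed RNAs, of which 8 were higher in both siYAP1 libraries 2 and 3 than in every siNC library. The summed level of the 6 was 1264 and 1915 CPM in siYAP1 libraries 2 and 3 against 274 CPM in siYAP1 library 1 and 283 to 294 CPM in siNC. Loss of YAP1 as the sole cause is argued against, since YAP1 was at 6.58 CPM in library 1 and 0 of the 6 were higher there than in every siNC library (2 of the class of 16 were). Incomplete selection of polyadenylated RNA in libraries 2 and 3 predicts a rise of histone mRNAs, which also lack the tail. Over 15 histone genes the median log2 difference of libraries 2 and 3 from library 1 was 1.81 (bootstrap 95% interval 0.997 to 2.29). Of these genes 12 were higher in both libraries than in library 1. The bootstrap resampled genes, which may move together, so its interval measures no spread between libraries. Incomplete selection may be the source, as a hypothesis.

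The YAP/TAZ target list, taken from targets described across cancer cell lines, was not lower as a whole after siYAP1. It had 8 targets lower, 4 higher and 9 uncalled. Too few reads to see a fall of 1.5-fold are argued against by the 95% intervals of the uncalled targets' log2 fold changes. They reached a median of 0.112 to either side (0.0775 to 0.405 over the targets). Where they were widest, a fall as small as that called for CYR61 (-0.16) could have been missed. A rise in RNA of the paralog WWTR1 is argued against by its log2 fold change of -0.20. That call ended without siYAP1 library 3 (edgeR adjusted p 0.0501), and the change was -0.16 without siYAP1 libraries 2 and 3. WWTR1 was at 337 to 370 CPM in siNC and 291 to 324 CPM in siYAP1. YAP1 was at 63.4 to 68.3 and 6.07 to 6.68 CPM there, without adjustment for gene length. The lack of a rise thus does not speak against TAZ acting at the level already present. That these targets do not respond to YAP in HUVEC stays open: 7 of the 9 passed the test with Ad-YAP-S127A, 3 higher and 4 lower, where 54.3% of all tested genes passed (Fisher's exact test, one-sided p 0.140, and 0.439 for the higher ones alone). TAZ protein acting on the targets, residual YAP protein and the time of sampling could each be involved and stay open, since RNA counts do not measure them.

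Genes lower with Ad-YAP-S127A were more frequent than expected for independent lists both among genes lower after siYAP1 (odds ratio 1.62) and among genes higher (1.58). The excess was thus not particular to 1 direction after siYAP1. The odds ratios and intervals here take genes as independent and measure no spread between libraries. Explanations were tested for the genes lower in both. Trends with GC content and transcript length do not account for all of it, since with both removed the odds ratio was 1.52 (1.38 to 1.68). Genes with more reads passing both tests more often do not either, since within strata of mean expression the common odds ratio (Mantel-Haenszel) was 1.54 (1.38 to 1.71). A shared response to transfection or infection with an active agent against a control agent, or a non-linear response to YAP, may be involved and was not tested, and a response in 1 shared direction would leave the reverse pair open.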

How the results depend on the processing

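Chosen after seeing the data were the removal of GC and length trends, with and without the replicate block, the run without siYAP1 libraries 2 and 3, the run without YAP1, and the separate spreads for the difference of effects. YAP1 kept its direction and its call in both experiments under every alternative run. Of the list calls, 0 held with an estimated correlation in either experiment. Over all alternatives, with fry, which sets a list against no change and not against other genes, the adjusted p after siYAP1 ran from 3.77e-13 to 0.142 for cholesterol synthesis genes, 9.92e-05 to 0.136 for both the TGF-beta and the p53 list, 0.000319 to 0.753 for glycolysis genes and MYC, 0.00168 to 0.688 for NF-kB genes and 0.00132 to 0.527 for epithelial markers. With Ad-YAP-S127A it ran from 1.68e-08 to 0.608 for endothelial identity genes, 0.00504 to 0.648 for Notch genes, 0.000255 to 0.608 for p53 targets, 0.000482 to 0.707 for cholesterol synthesis genes, 3.10e-05 to 0.728 for mitotic genes and 0.00443 to 0.707 for DNA replication genes. For lists called under some alternatives only, it ran with Ad-YAP-S127A from 0.0292 to 0.707 for Hippo components, 0.0316 to 0.707 for angiogenic factors, 0.0304 to 0.707 for extracellular matrix genes, and 0.00460 to 0.707 for lymphatic markers and flow-responsive genes, and, called with fry alone, 0.0177 to 0.707 for ATF4 response genes, 0.0471 to 0.886 for smooth muscle markers and 0.0471 to 0.707 for fibroblast markers. After siYAP1 it ran from 0.0468 to 0.799 for mitotic genes, 0.0176 to 0.688 for ATF4 response genes and 0.000982 to 0.755 for mitochondrial genes, and, called with fry alone, 0.000981 to 0.527 for flow-responsive genes, 0.00222 to 0.527 for actin genes and 0.0113 to 0.688 for lymphatic markers.

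With an absolute log2 fold change of at least 1, 156 genes were higher and 78 lower after siYAP1, and 1284 and 1995 with Ad-YAP-S127A. In the fit of all 10 libraries, 1198 were higher and 1113 lower after siYAP1, and without siYAP1 libraries 2 and 3, 1060 and 892, with a lone siYAP1 library assumed to vary like siNC. Ad-YAP-S127A lists called were 11 with fry, 11 without a filter and 10 in the fit of all 10 libraries. Genes lower after siYAP1 and higher with Ad-YAP-S127A numbered 773 at an unadjusted p under 0.05.

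Leaving out 1 library in turn left a lone adenovirus library assumed to vary like the other group. Genes higher ran from 2373 (without Ad-YAP-S127A library 1; 2538 without library 2) to 3922 with Ad-YAP-S127A and from 1494 to 1857 after siYAP1. Shared genes ran from 330 to 529 and the correlation across genes from -0.0675 to -0.0311. Adjusted p values of lists that turned direction ran from 0.515 to 0.979 for endothelial identity genes, 0.284 to 0.894 for extracellular matrix genes and 0.530 to 0.848 for smooth muscle markers after siYAP1. With Ad-YAP-S127A they ran from 0.655 to 0.956 for NF-kB genes, 0.810 to 0.850 for TGF-beta genes, 0.474 to 0.873 for glycolysis genes and 0.0512 to 0.749 for mitochondrial genes. None of these lists was called where it turned, and the cause was not tested. Of the genes the rule named, ASS1, CCNB1, CLDN7, CXCL11, DLL1, FAS, HEY2, MKI67, PTGIS and TEAD3 after siYAP1, and EPCAM, SYNPO2 and ACTA2 with Ad-YAP-S127A, also lost their call without some library. After siYAP1, 19 lost it without siYAP1 libraries 2 and 3 (CDC45 and DDIT3 besides those already named), 18 in the fit of all 10 libraries, 9 with DESeq2 and 4 with thinned counts. With Ad-YAP-S127A, 5 did without a filter.

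Lists that turned direction elsewhere, with adjusted p, were smooth muscle markers after siYAP1 without a filter (0.629) and without siYAP1 libraries 2 and 3 (0.736), leukocyte markers with at least 1 CPM (0.956) and with thinned counts (0.943), and endothelial identity genes in the fit of all 10 libraries (0.955), with the replicate block and trends removed (0.968) and without siYAP1 libraries 2 and 3 (0.989). With Ad-YAP-S127A these were actin genes with fry (0.710) and NF-kB genes with library totals alone (0.931), trends removed (0.932) and the replicate block with trends removed (0.982). The cause was not tested.

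Replicate numbers were not shown to pair libraries. Correlations of same-numbered siRNA libraries' deviations from their group means were 0.075, 0.033 and 0.044 over all tested genes, 0.178, 0.218 and 0.077 at 5 CPM or more, and 0.206, 0.221 and 0.124 at a mean log2 CPM over 3, where all pass 0.1. The outcome depends on the gene set. Every siRNA library correlated best with its own number, a hint from the data alone. The adenovirus pairs gave 0.191, 0.402 and 0.448. With the replicate block 2324 genes were higher and 2209 lower after siYAP1, with 5 lists, and 4571 and 4675 with Ad-YAP-S127A, with 6 lists. Shared genes were then 707, genes whose effects differ 8993, the correlation -0.0478 and the YAP1 log2 fold changes -3.35 and 9.68. The block changed the calls of NF-kB genes, epithelial markers and mitochondrial genes after siYAP1 and of no other list.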

Other observations

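The gene families in the next paragraphs and their tests were chosen after the results were seen: 19 families, some narrowed after a first look, adjusted over 38 tests. HOX genes, which set position along the body axis, were higher with Ad-YAP-S127A: 18 of 26 rose and 2 fell, with a median log2 fold change of 1.44 (camera adjusted p 0.000175; adjusted p 0.488 with an estimated correlation). HOXA10 went from 15.9 ± 0.446 to 109 ± 6.11 CPM (SD, n = 2), HOXA11 from 18.9 ± 0.852 to 131 ± 15.5 CPM and HOXA7 from 5.84 ± 0.537 to 67.1 ± 7.25 CPM, while HOXD8 fell from 31.3 ± 3.27 to 15.4 ± 0.00426 CPM. EREG, an EGF receptor ligand like AREG and picked after its values were seen, had 0 counts in Ad-NC and 281 in Ad-YAP-S127A, at least 88.9-fold higher against a floor of 3 counts over the group.

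Genes of cytosolic ribosomal proteins were lower with Ad-YAP-S127A, with 71 of 79 lower and 1 higher and a median log2 fold change of -0.82 (camera adjusted p 3.30e-13; adjusted p 0.475 with an estimated correlation). RPL3 was at -0.91 and RPL10 at -1.16. With library totals alone, which move the median of all genes by 0.14, the median was -0.69, with 70 lower and 3 higher. Host genes of small nucleolar RNAs had 12 of 21 lower and 0 higher (camera adjusted p 0.00576; adjusted p 0.475 with an estimated correlation), with GAS5 at -1.23 and SNHG1 at -1.21. Clustered protocadherin genes, whose transcripts share exons so that reads of single members are uncertain, had 34 of 35 lower and 0 higher (camera adjusted p 9.54e-12; adjusted p 0.475 with an estimated correlation), and ADAMTS proteases 8 of 11 lower and 1 higher (camera adjusted p 0.00460; adjusted p 0.475 with an estimated correlation). Numbered zinc finger genes had 154 of 428 lower and 48 higher, with a median log2 fold change of -0.22 (camera adjusted p 0.0116; adjusted p 0.568 with an estimated correlation), and 121 lower and 67 higher with library totals alone. All of these directions were kept with RLE scaling, library totals alone and trends with GC content and length removed.

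After siYAP1, translation initiation factor genes had 16 of 60 lower and 2 higher with a median log2 fold change of -0.07 (camera adjusted p 0.00418; adjusted p 0.475 with an estimated correlation). Small nucleolar RNA host genes had 6 of 21 lower and 0 higher (camera adjusted p 0.00634; adjusted p 0.475 with an estimated correlation), and ribosomal protein genes 9 of 79 lower and 0 higher (camera adjusted p 0.00847; adjusted p 0.639 with an estimated correlation), where 1870 of all 14190 tested genes were lower. With library totals alone 4 ribosomal protein genes were lower and their median moved from -0.04 to -0.02. Keratin genes, which include the epithelial markers KRT7, KRT8 and KRT18, had 4 of 7 lower and 1 higher (camera adjusted p 0.0253; adjusted p 0.475 with an estimated correlation), and apolipoprotein L genes 3 of 5 higher and 0 lower (camera adjusted p 0.0263; adjusted p 0.475 with an estimated correlation). Interleukins and their receptors had 11 of 32 higher and 4 lower (camera adjusted p 0.0350; adjusted p 0.475 with an estimated correlation).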
